A study of Mus musculus with 10 samples.

How the data were processed

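Chromatin carrying trimethylated lysine 27 of histone H3 (H3K27me3), a mark of Polycomb repression, was immunoprecipitated and sequenced from mouse bone marrow-derived macrophages. Marrow cells were grown for 7 days with 20 ng/ml M-CSF, the growth factor that turns marrow progenitors into macrophages. They were then left untreated (M0), stimulated for 24 h with 20 ng/ml LPS and 50 ng/ml interferon-gamma (M1), or stimulated for 24 h with 20 ng/ml IL-4 (M2). Wild type (WT) cells carried a floxed Eif2ak3 gene, which encodes the stress kinase PERK, and knockout (KO) cells also carried Cre recombinase driven by the lysozyme M gene, which is active in myeloid cells. There were 10 libraries: 1 per genotype in M0 and 2 per genotype in M1 and in M2. The series' design text describes the M1 and M2 libraries as separate biological samples, so p-values measure the spread between those cultures, and M0 has no replicate within a genotype.

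Per the submitters' processing notes, the tools included Bowtie2 2.4.2, SAMtools 1.10, deepTools 3.5.1, HOMER 4.8 and DiffBind 2.0.2, with the mm10 mouse genome build. The authors called regions separately in each library, without an input control, with HOMER findPeaks in its region mode, per the file headers. Windows of 1000 bp were joined into regions across gaps of up to 2500 bp, at a false discovery rate of 0.001, per the file headers. The headers of the 10 lists also give the total tags of each library, which ran from 12.6 to 20.9 megatags, and the share of tags inside called regions, which ran from 41.3% to 64.1%. With so many tags the 95% Wilson interval of such a share is at most 0.0267 percentage points to either side, which covers counting error only.

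The signal column of each region list holds the authors' tag count normalised to 10 megatags, per the file headers. Each region also has the authors' score and a ratio called clonal fold change, per the file headers. The score and the signal were used only to rank regions within a list. The 4 deposited tables of differential regions give the authors' concentrations and fold on a log2 scale. They also give the authors' p-value and false discovery rate for each region, and the signs show that a positive fold stands for more H3K27me3 in KO. Every listed region is 401 bp wide and has a p-value under 0.01, as read from the tables. The libraries, the scaling and the statistical model behind these tables are not given in the sources used here.

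Values computed from these files were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Overlapping regions of a library were merged and the genome was divided into 1 kb bins. A bin counted as called in a library when at least 50% of it lay under that library's regions. Pairs of libraries were compared by the Jaccard index, the shared covered length divided by the joint covered length. A protein-coding gene counted as covered when at least 50% of its body lay under called regions. Gene positions came from a RefSeq table of the GRCm38.p6 assembly, the same build as mm10, with 21887 protein-coding genes on the autosomes, X and Y. That table holds no strand, so the promoter windows planned before the data were examined could not be placed, and the gene body took their place. An authors' region was assigned to every protein-coding gene whose body, with 5 kb on either side, it touched. Position in an exon, intron or untranslated region was not analysed here.

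Genotypes were compared by exact two-sided permutation of the WT and KO labels within each state, which gives 72 arrangements and a smallest p of 0.0278. M1 and M2 were compared by exact two-sided permutation over 8 libraries, with 70 arrangements and a smallest p of 0.0286. Within M1 or within M2 alone, 2 libraries against 2 cannot give a p under 0.333. For bins and genes, the count called in all libraries of one group and none of the other was set against every other split of the same libraries. The coverage, bin and permutation steps were tested on simulated data: 300 of 300 covered lengths matched a base-by-base count, and 200 of 200 planted bins were found with 0 false ones. For the genotype test over 10 libraries, 10 of 300 simulated sets without a difference and 295 of 300 sets shifted by 4 SD had p under 0.05.

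Gene lists were written before the data were examined: 12 lists with 366 distinct genes, of which 365 were matched to the gene table. They cover IL-4 responses, LPS and interferon responses, the integrated stress response with serine synthesis, the H3K27 methylation machinery, Hox genes, developmental transcription factors, macrophage identity, housekeeping genes, and the tricarboxylic acid cycle with respiration. The remaining 3 lists hold markers of lymphoid cells, of granulocytes, erythroid and dendritic cells, and of stromal and epithelial cells. Enrichment of a list among genes near the authors' regions used Fisher's exact test. The background was all genes that a called region of that state could be assigned to, with Benjamini-Hochberg adjustment over the 12 lists.

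The genes named in the text follow a rule also written before the data were examined. Among regions with an assigned gene, it takes the genes at the 12 smallest p-values of the M2 KO enriched table and at the 6 smallest of each other table, and every listed gene near an authors' region. It adds list genes covered in all libraries of M1 or of M2 and none of the other, and any gene covered in all libraries of one genotype and none of the other. Eif2ak3, Irf4, Pparg, Arg1, Mgl2, Retnla, Nos2, Il6, Il12b and Actb are always given. Genes outside the rule are marked as chosen after their values were seen, and values of some single genes are not reported here. Alternatives included equal numbers of regions per library, the upper 50% of each list by score, autosomes only, other bin lengths and limits, and leaving out each library in turn.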

Results

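H3K27me3 regions were called in 10 macrophage libraries, 5 WT and 5 KO for Eif2ak3, the gene of the stress kinase PERK. The M0 libraries held 12.6 megatags in WT and 14.5 megatags in KO, the 4 M1 libraries 18.4 to 19.9 megatags, and the 4 M2 libraries 14.2 to 20.9 megatags. Each library had between 32320 and 39658 called regions. Stimulated libraries had 214 to 251 Mb under regions, against 157 Mb in WT M0 and 177 Mb in KO M0. The M0 libraries also differed in estimated fragment length, 352 and 372 bp against 178 to 190 bp in the stimulated libraries, so M0 is set beside the stimulated states as values only. Both WT replicate 1 libraries, in M1 and in M2, stood apart on the X chromosome, where 18.4% and 31.1% of the 1 kb bins were called against 0.404% to 0.588% in the other 8 libraries.

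**Figure D1:**
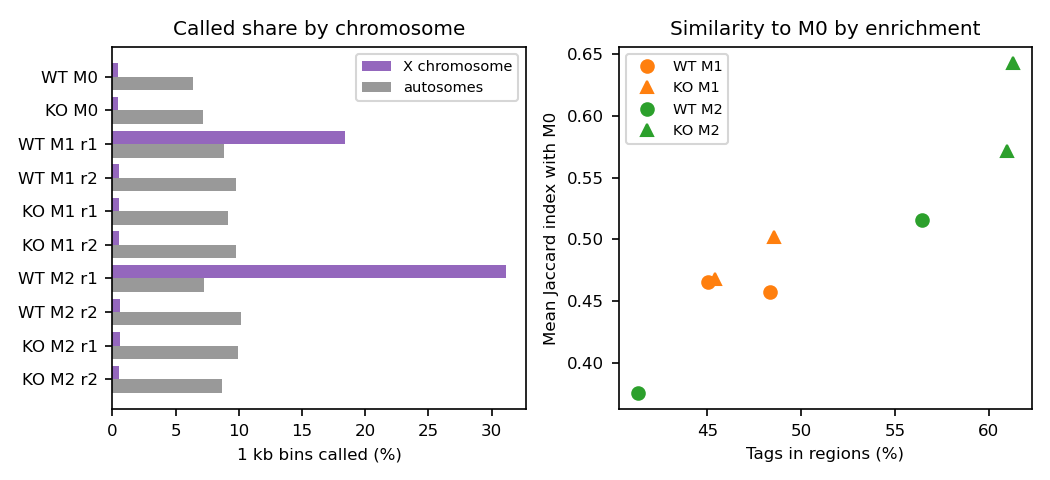
Left, percent of 1 kb bins called on the X chromosome and on the autosomes (horizontal axis) in each of the 10 libraries, with the WT replicate 1 libraries at 18.4% and 31.1% of X. Right, mean Jaccard index with the M0 libraries against the percent of tags in regions for the 8 stimulated libraries, each point a library, with KO M2 at 0.572 and 0.643 and the rest between 0.376 and 0.515.

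The Eif2ak3 gene body itself (chromosome 6, 70844484 to 70905241, mm10) lay outside called regions in all 10 libraries, at 0% covered. H3K27me3 cover does not test the deletion, so the genotypes rest on the labels. Polycomb targets were covered in every library: 36 to 38 of the 39 Hox genes, which set body pattern in the embryo, and 51 to 54 of 60 developmental transcription factors, with 35 and 50 of them covered in all 10. None of 20 housekeeping genes, Actb among them, was covered in any library. Of the lymphoid markers, 10 to 14 of 24 were covered per library, and 8 in all 10. Macrophage identity genes were largely free of cover by this measure, with 0 of 24 genes covered in the M1 libraries, 0 or 1 in the M2 libraries and 2 and 3 in M0. Of 25 genes of the integrated stress response and serine synthesis, 0 to 2 were covered per library, and of 32 genes of the tricarboxylic acid cycle and respiration only the X-linked Idh3g, in WT M2 replicate 1, a gene chosen after its values were seen. Of 19 genes of the H3K27 methylation machinery 2 to 5 were covered, with Cbx7 and Cbx8, chosen after their values were seen, in all 10 libraries. Markers of granulocytes, erythroid and dendritic cells were covered in 6 to 10 of 24 and stromal and epithelial markers in 3 to 8 of 20.

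The first comparison asked where H3K27me3 differed between the inflammatory M1 and the IL-4 driven M2 state. Nos2, which encodes the inducible nitric oxide synthase of M1 macrophages (chromosome 11, 78920787 to 78960226), had 89.5% ± 4.87 of its body covered in M2 and 6.86% ± 5.76 in M1 (SD, n = 4 each). Socs3, a feedback inhibitor of cytokine signalling (chromosome 11, 117966079 to 117970336), had 67.1% ± 6.28 covered in M2 and 0% in all 4 M1 libraries. Both genes were covered in both M0 libraries, Nos2 at 89.6% and 92.8% and Socs3 at 100%. These were the only genes of the 12 fixed lists covered in all 4 libraries of one stimulated state and none of the other. In the other direction, Egr2, an IL-4 induced transcription factor chosen after its values were seen, had 83.2% ± 1.75 of its body covered in M1 and 50.3% ± 10.4 in M2 (chromosome 10, 67534469 to 67542188). Each of the 3 differences separated the groups fully, at p = 0.0286 in an exact permutation test with n = 4, the smallest this design gives. Of 216 list genes with any cover, 6 were separated in this way, 3 in each direction, and chance alone gives 2.86% of genes or 6.17; adjusted over the list alone, the smallest p was 1. With only the upper 50% of each list by score, Socs3 differed by 35.2 percentage points (exact permutation p = 0.429, n = 4) and Egr2 by -17.9 (exact permutation p = 0.543, n = 4).

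By the measure of 50% of the gene body, most genes of both activation programmes were not covered in either state. Marks confined to a smaller part of a gene are missed by this measure. Of the 39 measured LPS and interferon genes, 33 were covered in no library, among them Il6 and Il12b, while Ciita and Il12a, chosen after their values were seen, were covered in all 10. The count covered per library was 4 in each M1 library and 5.5 ± 1.00 in M2 (SD, n = 4; exact permutation p = 0.143, adjusted p = 1). Without WT M2 replicate 1, which had 4, the difference was 2 genes (exact permutation p = 0.0286, n = 3 and 4, not adjusted). These 2 genes are Nos2 and Socs3, reported above for the same separation, so this p is no separate evidence for the list. Of the 40 IL-4 genes, 25 were covered in no library, among them Arg1, Retnla, Pparg and Irf4, and Ccl24, chosen after its values were seen, in all 10. The count was 7.5 ± 0.577 in M1 and 7.0 ± 2.94 in M2 (SD, n = 4; exact permutation p = 0.914, adjusted p = 1), and the difference of -0.5 turned to 0.833 without WT M2 replicate 1. Irf4, a transcription factor of the IL-4 programme, had 15.3% to 22.2% of its body covered across all 10 libraries, and Pparg at most 1.39%. Il6 was covered at 20.2% in KO M1 replicate 1 alone, and Il12b at 5.41% and 6.24% in the M0 libraries alone. With all libraries and regions, no list passed a threshold of 0.05 in the exact permutation tests of state or genotype, adjusted or unadjusted. The LPS and interferon list reached p = 0.0286, unadjusted, also with the upper 50% of regions by score and with 25% of the gene body, each with a difference of 2.25 genes (exact permutation, n = 4). The list holds Nos2 and Socs3, so these values are not independent of the differences of those 2 genes.

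**Figure D2:**
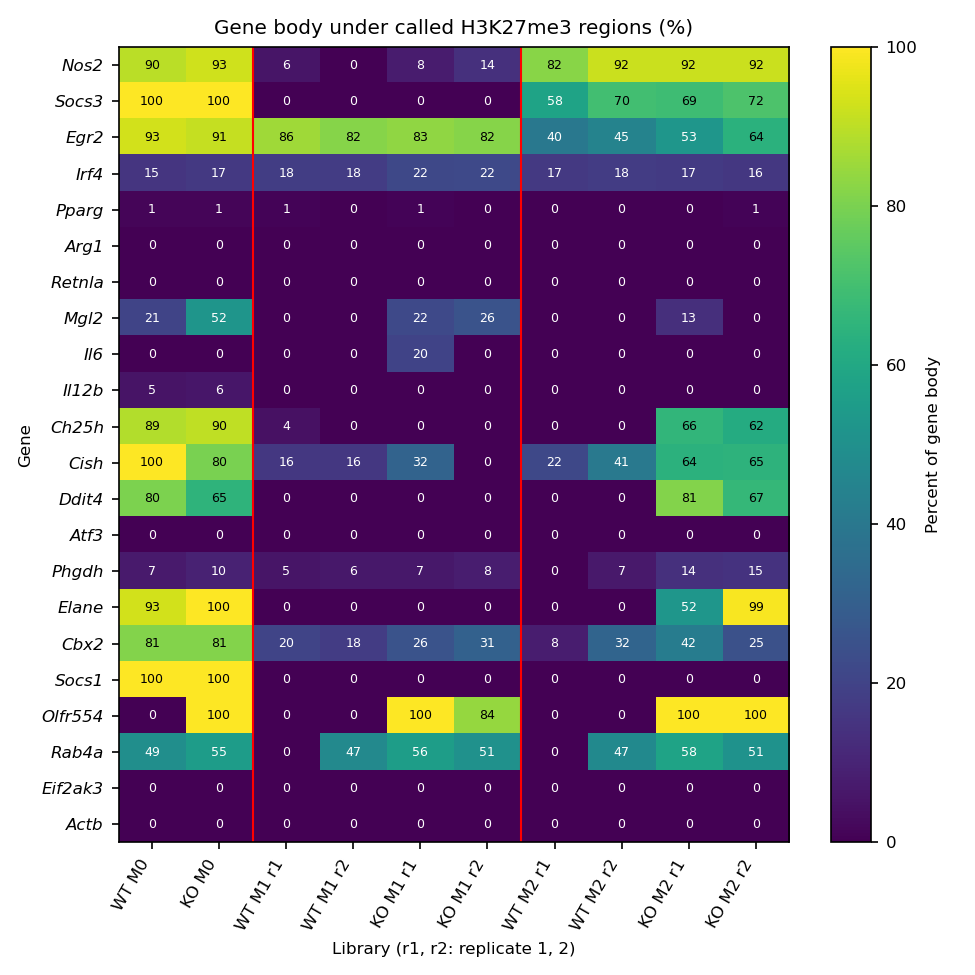
Percent of each gene body (vertical axis, 22 genes) under called H3K27me3 regions in the 10 libraries (horizontal axis, with red lines between M0, M1 and M2 and r1 and r2 for replicates). Nos2 lies between 82.2% and 92.0% in the 4 M2 libraries and at most 14.0% in the 4 M1 libraries, and Ch25h and Ddit4 are covered in M0 and in KO M2.

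Over all protein-coding genes, 6 were covered in all 4 M1 and no M2 library and 2, Nos2 and Socs3, in the reverse direction. The 6 were Apol7c, Gm12169, Ltb4r1, Olfr985, Rab30 and Tmprss4, named after their values were seen. WT M2 replicate 1, whose mean Jaccard index with the other M2 libraries was 0.477 against 0.708 among those 3, sets the second number: without it 88 genes were covered in all remaining M2 libraries and no M1 library, and 10 in the reverse direction. Without WT M1 replicate 1 the numbers were 6 and 16. In 1 kb bins, 1061 kb was called in all 4 M1 and no M2 library and 544 kb in the reverse, 0.253% and 0.130% of the 419201 kb called in any stimulated library. Without WT M2 replicate 1 these lengths were 2098 and 4159 kb. Region number (M2 34530 ± 1394, M1 34739 ± 3335; SD, n = 4; exact permutation p = 0.943) and covered length (M2 235.7 ± 16.5 Mb, M1 239.3 ± 8.88 Mb; exact permutation p = 0.743) differed by less than the spread between libraries. The mean Jaccard index of same-state pairs lay 0.0128 above that of different-state pairs (exact permutation p = 0.60, n = 4).

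The central comparison asked whether loss of PERK changes H3K27me3, above all after IL-4. The authors' deposited tables for M2 list 1049 regions as KO enriched and 185 as WT enriched, at p-values under 0.01. Only 3 of these pass a false discovery rate of 0.05. In the authors' deposited table the KO enriched one lies within Ift122 (chromosome 6, 115919888 to 115920288), a gene of ciliary transport, with a log2 fold of 3.43 and a false discovery rate of 0.00699. The authors' deposited table of WT enriched regions holds the other two, the first on chromosome 13 (19341767 to 19342167) with no protein-coding gene within 5 kb, at a log2 fold of -3.94 and a false discovery rate of 0.00294. The second lies 5.43 kb from Iigp1, an interferon-inducible GTPase named after the table was seen, on chromosome 18 (60367790 to 60368190), with a log2 fold of -4.03 and a false discovery rate of 0.0236 in the authors' deposited table. The Ift122 region was called in both KO M2 and no WT M2 library, and both WT enriched regions in both WT M2 and no KO M2 library. The regions were picked for that M2 difference, so these calls are no separate evidence. Elsewhere the Ift122 region was called in both M0 libraries and WT M1 replicate 2. The chromosome 13 region was called in WT M1 replicate 2 and KO M1 replicate 1, and the chromosome 18 region in WT M1 replicate 2 and both KO M1 libraries. The median log2 fold of the authors' deposited tables was 1.49 for the KO enriched and -1.99 for the WT enriched M2 regions. From the authors' false discovery rates, 25401 regions were tested in M2, of which about 254 would lie under p = 0.01 by chance.

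Among genes near KO enriched M2 regions were 3 members of the stress response and serine list, of 13 in the background. They were Phgdh, the first enzyme of serine synthesis, with a log2 fold of 1.35 in the authors' deposited table, Ddit4, a stress-induced inhibitor of mTOR signalling (log2 fold 2.69), and Atf3, a stress-induced transcription factor (log2 fold 1.79). Chance gives 0.858, and the share had p = 0.0499 in Fisher's exact test and an adjusted p of 0.299 over the 12 lists. The authors' deposited table also lists regions at Ch25h, the cholesterol 25-hydroxylase of the IL-4 list (log2 fold 1.29), at the fractalkine receptor Cx3cr1 (1.82), at Pdgfrb (1.70) and Kdr (1.35) of the stromal list, at the T cell kinase Lck (1.39), and next to the globin Hba-a1 (1.24). No KO enriched M2 region was assigned to any of the 60 developmental transcription factors, where 3.96 are expected by chance (Fisher's exact test, p = 0.0326, adjusted p = 0.299), nor was a region of the other 3 sets. The tests of gene lists were not matched for gene length, so their chance values take all genes as equally likely. Genes near KO enriched M2 regions had a median length of 48.0 kb, against 21.4 kb in the background shared by M1 and M2. None of the 12 lists was enriched after adjustment near any of the 4 sets of regions, and Irf4, Pparg, Arg1, Mgl2, Retnla and Nos2 were near none of them. In the authors' deposited tables, a false discovery rate under 0.1 was reached by 4 KO enriched and 3 WT enriched M2 regions, of which only the one in Ift122 has a protein-coding gene within 5 kb. Among KO enriched M2 regions with such a gene, the smallest p-values of the authors' deposited table stood at Ift122, Tmem53 with Armh1, Angpt4, Arc, Abca8b, Usp2, Cbs, Clstn3, Kdm5b with Mgat4e, Fbrsl1, Gprc5a and Myrip, with log2 folds from 1.87 to 3.43 and false discovery rates of 0.105 apart from Ift122. Cbs encodes the cystathionine synthase that consumes serine, and Kdm5b a histone demethylase of lysine 4. On the WT enriched side, again only among regions with such a gene, these were Wdr27, Pde8b, Shox2, Rims2, Slc5a4a and Dock3, with log2 folds from -3.23 to -1.97.

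At whole-gene level, Ch25h (chromosome 19, 34473783 to 34475148) had 63.7% ± 2.95 of its body covered in KO M2 and 0% in both WT M2 libraries (SD, n = 2). Ddit4 (chromosome 10, 59949675 to 59951770) had 74.0% ± 10.4 covered in KO M2 and 0% in WT M2. Both were covered in both M0 libraries and in none of the M1 libraries. Gene bodies did not all follow the nearby regions: Hba-a1 had 21.8% and 10.1% covered in KO M2 and 100% in both WT M2 libraries, and Atf3 had 0% in all 10 libraries. Such differences of 2 libraries against 2 cannot fall under p = 0.333 in an exact permutation test. Ch25h and Ddit4, with bodies of 1.37 and 2.10 kb, were named for KO enriched regions 0.561 and 0.4 kb away. Those regions were picked for the M2 difference, so the M2 cover of these 2 genes is no separate evidence. Over all 10 libraries the IL-4 genes covered were 8.6 ± 1.34 in KO and 7.0 ± 2.55 in WT (SD, n = 5; exact permutation p = 0.333, adjusted p = 1). WT M2 replicate 1 had the lowest count, 3 genes, and without it the difference of 1.6 genes was 0.615.

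The M1 tables were smaller. The authors' deposited tables list 93 KO enriched and 49 WT enriched M1 regions, with a false discovery rate of 1.00 throughout. By p-value, the KO enriched ones with a gene within 5 kb were led by Fbxo15, Peli2, Car5a, Tmprss4 with BC049352, Adgrv1 and Fmn1, and the WT enriched ones by Myrip, Magi1, Dlgap2, Mylk, Iqsec3 and Adcyap1r1. Myrip, which encodes a linker of myosin and Rab proteins, was thus WT enriched in M1 (log2 fold -1.80) and KO enriched in M2 (2.53) in the authors' deposited tables, at separate positions. Ptgs1, a prostaglandin synthase of the IL-4 list, was the only list gene near an M1 region, with a log2 fold of 1.44 in the authors' deposited table. KO enriched regions made up 85.0% of the M2 and 65.5% of the M1 entries (Fisher's exact test on regions, p = 9.3e-08). Regions are not independent replicates, so that p describes the tables, not the cultures. KO enriched regions of M1 and M2 shared 11 genes of 43 in M1, against 2.92 for independent tables (Fisher's exact test, p = 0.000101). A permutation test that drew genes of matched length 10000 times gave 4.29 shared genes on average and p = 0.0024. Chosen after their values were seen, the 11 include Abcb1a, Neo1 and Zfpm1 and the neighbours Oplah, Smpd5 and Spatc1, and 3 regions were shared. Neighbouring genes count separately in both tests, so the genes are not independent and these p-values describe the tables only. A test across directions was added, and the genes it shares chosen, after the values were seen. Of the 22 genes near WT enriched M1 regions, 5 (Gnao1, Iqsec3, Magi1, Myrip and Prkca) lay near KO enriched M2 regions, or 22.7% against 25.6% in the same KO direction, with 1.49 for independent tables (Fisher's exact test, p = 0.0142). This test was not matched for gene length, although those 22 genes had a median length of 168 kb against 21.4 kb in the background. Genes near KO enriched M1 and WT enriched M2 regions shared 1 of 43, against 0.250 (Fisher's exact test, p = 0.222). WT enriched regions shared 1 gene, Adarb2, chosen after its values were seen (Fisher's exact test, p = 0.12).

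The direction of each table was then read in the libraries of the other states, taken to lie outside it, although the libraries behind each table are not stated. The KO enriched M2 regions had 98.4% ± 0.642 of their length called in KO M2 and 45.3% ± 14.6 in WT M2 (SD, n = 2). In the M0 and M1 libraries it was 66.0% ± 14.6 in KO and 61.5% ± 13.2 in WT (SD, n = 3; exact permutation p = 0.50, smallest possible 0.167). The WT enriched M2 regions had 83.2% ± 12.6 called in WT M2, 8.42% ± 3.45 in KO M2, and 32.6% ± 26.9 in KO against 34.7% ± 32.3 in WT elsewhere (exact permutation p = 1, n = 3). For the M1 regions the differences elsewhere were 6.52 percentage points for KO enriched (exact permutation p = 0.667, n = 3) and 6.02 for WT enriched ones (exact permutation p = 0.50, n = 3). Without WT M2 replicate 1 these were -1.41 and -0.270. The SDs over M0 and M1 libraries also hold the gap between those states. Within M1 alone, cover of the KO enriched M2 regions was 57.9% ± 6.15 in KO and 53.9% ± 0.395 in WT (SD, n = 2). For the WT enriched M2 regions it was 47.3% ± 12.3 in KO and 50.9% ± 22.7 in WT. As the smallest possible p is 0.167, these tests cannot decide whether a table's direction holds in the other states. By state, M0 libraries covered 76.7% and 82.1% of the KO enriched M2 length and 2.32% and 3.13% of the WT enriched M2 length, while M1 libraries covered 53.5% to 62.2% and 34.9% to 67.0%.

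**Figure D3:**
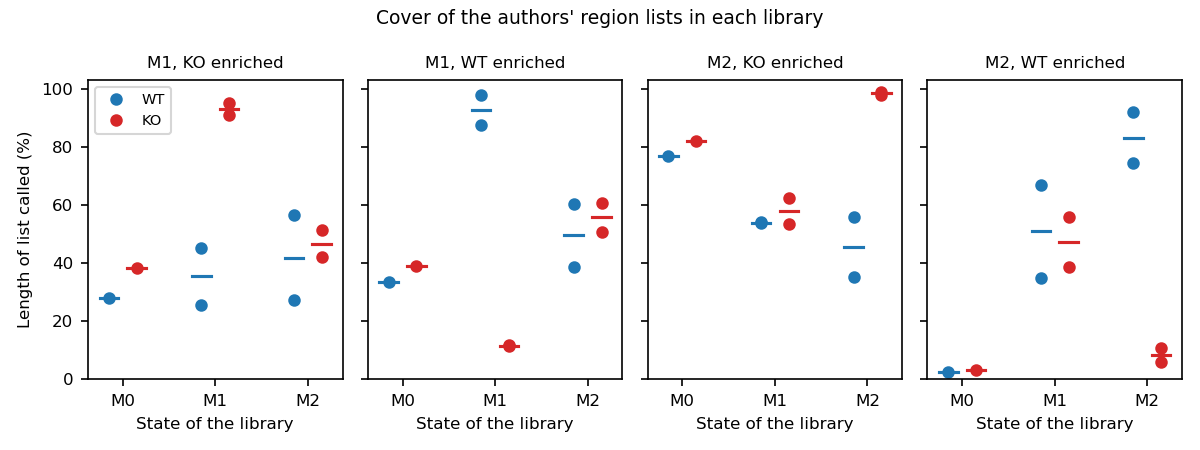
Percent of the length of each of the authors' 4 sets of regions (panels) that is called in each library, by state, with WT in blue and KO in red; points are libraries and lines are means. KO M2 libraries cover at least 97.9% of the KO enriched M2 regions, and both M0 libraries cover at least 76.7% of them.

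Region number and covered length did not differ between genotypes by more than the spread between libraries. Region number was 34130 ± 1724 in KO and 35149 ± 2914 in WT (SD, n = 5; exact permutation p = 0.611), and covered length 221.0 ± 27.8 Mb and 225.7 ± 39.2 Mb (exact permutation p = 0.556). On autosomes alone the signs turned, to 1915 more regions (exact permutation p = 0.25) and 11.8 Mb more in KO (exact permutation p = 0.472). The SDs of covered length over all states also hold the gap between M0 and the stimulated states. Over all chromosomes, KO minus WT was -9.94 Mb within M1 and -11.8 Mb within M2 (exact permutation p = 0.667 each, n = 2). In M0 the covered length was 177 Mb in KO and 157 Mb in WT. In M2, 13026 kb was called in both KO and no WT library and 11413 kb in the reverse. The other pairings of these 4 libraries gave totals of 8404 and 16653 kb against 24439 kb. In M1 the lengths were 7345 kb for KO and 5982 kb for WT, a total of 13327 kb that both other pairings exceeded with 14812 and 18898 kb. Leaving out a library means that fewer libraries have to share a bin, and these lengths rose to at most 57603 and 75981 kb in M2, both without WT M2 replicate 2, and to 27061 kb without KO M1 replicate 1 and 50904 kb without WT M1 replicate 2 in M1. Over all states, 105 kb was called in all 5 KO and no WT library and 8 kb in the reverse, out of 430935 kb called in any library. This excess turned without WT M0, to 302 kb in KO only and 372 kb in WT only, and without both M0 libraries the lengths were 485 and 380 kb. Within states, the mean Jaccard index of same-genotype pairs lay 0.00174 above that of different-genotype pairs (exact permutation p = 1).

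Covered in all 5 KO libraries and no WT library were 2 genes, and 0 genes were covered in all 5 WT and no KO library. Olfr554, an olfactory receptor gene (chromosome 7, 102640248 to 102641201), had 84.3% to 100% of its 0.954 kb body covered in the 5 KO libraries and 0% in the 5 WT libraries. Rab4a, a small GTPase of endosomal recycling (chromosome 8, 123805846 to 123835291), lay at 50.7% to 58.1% in KO. In WT it lay at 49.2% in M0, 46.9% and 47.3% in both replicate 2 libraries and 0% in both replicate 1 libraries, so 3 WT values fall just under the 50% limit. Being picked for this separation from 21887 genes, both have the smallest possible exact permutation p of 0.0278 (n = 5, not adjusted). Of 40 genes that were named near the authors' regions and differed between libraries, 3 had that p, where chance gives 1.11. These were Phgdh (KO minus WT 5.40 percentage points of the gene body), Fbrsl1 (1.99) and Dlgap2 (-4.73). Their naming rests on M1 or M2 differences between the genotypes, so that p is no independent evidence. The share of tags in regions was 61.0% and 61.3% in KO M2 and 41.3% and 56.5% in WT M2, while in M1 the genotypes overlapped between 45.0% and 48.5%.

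The last comparison set the stimulated libraries beside the M0 library of the same genotype, as values without a test. KO M2 libraries kept 88.0% and 88.8% of the M0 bins, WT M2 68.0% and 87.1%, KO M1 73.2% and 80.3%, and WT M1 79.9% and 80.3%. Genes covered in both M0 and no stimulated library numbered 59. Chosen after their values were seen, these include the Polycomb genes Bmi1 and Cbx2 and the cytokine signalling inhibitor Socs1, which was covered at 100% in both M0 libraries and at 0% in all 8 others. In the reverse direction, 122 genes were covered in all 8 stimulated libraries and neither M0 library, such as Il5, Il33, Ikzf3 and Ncr1, also chosen after their values were seen. Of the 45 ways to pick 2 of the 10 libraries, the highest other counts were 226, for both WT replicate 1 libraries, and 46. Of those 226 genes, 225 lie on the X chromosome, where these 2 libraries stood apart, and 1 lies elsewhere. The M0 libraries are also the ones that differ from the stimulated libraries in fragment length.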

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

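The tests of enrichment, of the WT M2 replicate 1 library, of X chromosome regions and of depth, the comparison of bins with other groupings, and the groupings of genes under other settings, were chosen only after the result was seen; the tests of X and Y cover were set down earlier. Of 86 groups of libraries tested for a library far from the rest, 18 held one. Chance gives about 1 in 20 groups, or 4.3, for continuous values, but in 9 of the 18 all other libraries had the same gene count, so a step of 1 gene is enough and the 2 numbers cannot be compared. In 21 exact permutation tests of whether the genotype difference depends on the state the smallest p was 0.278, in a design that cannot give a p under 0.0556.

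Both WT replicate 1 libraries held H3K27me3 that the rest of their state lacked. On the X chromosome 18.4% of bins were called in WT M1 replicate 1 and 31.1% in WT M2 replicate 1, with 291 and 434 of 966 X genes covered against 19 to 25 elsewhere, and 44922 kb was called in WT M1 replicate 1 alone within M1. Of the bins called in both of these libraries and no other stimulated one, 97.2% lay on X, so a candidate explanation is an inactive X chromosome of a female donor animal; donor sex is not in the labels. For lower enrichment as the cause, the bound set was that both have the lowest share of tags in regions of their state. WT M2 replicate 1 did, at 41.3%, but WT M1 replicate 1 did not, at 48.3%. That share includes tags in the extra X regions, so it cannot decide the question. On autosomes both had the lowest share of bins called of their state, 8.79% for WT M1 replicate 1 and 7.28% for WT M2 replicate 1. The Y chromosome left the question open. The bound set for an absent Y was missed, as 3 libraries had less of Y called than the higher of the WT replicate 1 libraries. However, at most 0.0176% of Y was called in any library. Of 24 kb of Y called in any library, 22 kb lay beyond 90.7 Mb, as did all 6 kb of the WT replicate 1 libraries. So few calls, nearly all at one place, cannot show whether Y was present.

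The authors' deposited tables held a larger KO enriched share in M2 than in M1, by 19.5 percentage points, in a test over regions that are not independent. X chromosome regions numbered 0 in the M2 tables, so no listed region lies on X. All 4 tables hold 0 regions on X or Y, which leaving out those chromosomes would also give. The scaling is not given either, so this count cannot decide whether the X signal of WT M2 replicate 1 affected the autosomal values. WT M2 replicate 2 called 55.7% of the KO enriched length, within the range of the M1 libraries, but regions picked for low WT M2 signal cannot decide whether WT M2 replicate 1 alone set the tables, and higher enrichment in KO M2 stays open too. The KO enriched M2 regions had a median concentration 0.83 higher on the log2 scale than the WT enriched ones, against 0.09 in M1, and both KO M2 shares of tags in regions lay above both WT M2 shares. With 2 libraries against 2, enrichment and loss of PERK cannot be told apart.

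KO M2 libraries were the stimulated libraries closest to M0, with mean Jaccard indices of 0.572 and 0.643. Across the 8 stimulated libraries the index rose with the share of tags in regions (Spearman rho 0.929, exact permutation p = 0.00223, adjusted p = 0.00223; Pearson r 0.923, exact permutation p = 0.000645; r 0.826 without both KO M2 libraries), so enrichment may set it. It fell with total tags as well (rho -0.952, exact permutation p = 0.00114, adjusted p = 0.00223; r -0.907, exact permutation p = 0.00223; r -0.611 without KO M2 replicate 2 and WT M2 replicate 1). The bound set for depth was missed by 0.768 megatags between KO M2 replicate 1 and WT M2 replicate 2, too little to exclude depth. Share and depth moved together (rho -0.857), and no library lay between 48.5% and 56.5% of tags in regions. The relation was not tested within the 5 libraries below or the 3 above that gap, so share, depth and genotype cannot be told apart. Length that M0 lacks also lowers the index, including the X bins of both WT replicate 1 libraries. Bins outside M0 of the same genotype made up 36.2% and 27.4% in KO M2, against 41.4% to 54.1% in other stimulated libraries. The M0 bins kept were 88.8% and 88.0% in KO M2, 87.1% in WT M2 replicate 2 and 68.0% to 80.3% in the rest. No test was run without X or at equal covered length.

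Covered length in WT M0, 157 Mb, lay far below the other WT libraries. The mean Jaccard index of WT M2 replicate 1 with the other M2 libraries, 0.477, lay far below theirs. Among M2 libraries, WT M2 replicate 1 also stood apart with 4 LPS and interferon genes, 3 genes of the H3K27 machinery, 36 Hox genes and 1 gene of the tricarboxylic acid cycle and respiration, and for the last also among WT libraries. Of its 3 machinery genes, the X-linked Rbbp7, chosen after its values were seen, was covered at 59.4% and counted as covered in no other library. KO M0 stood apart among KO libraries with 5 genes of the H3K27 machinery, a count that WT M0 shared, against 2 or 3 in the stimulated libraries, and WT M0 among WT libraries with 3 macrophage identity genes. KO M1 replicate 2 had 54 developmental transcription factors covered, and called 62.2% of the KO enriched M2 length, both above the other M1 libraries. KO M2 replicate 2 was the only M2 library with a macrophage identity gene covered, 1 of 24. Lymphoid markers numbered 14 in WT M2 replicate 2, above the other WT libraries, and 10 in KO M1 replicate 1, below the other KO libraries. KO M1 replicate 1 also lay below them with 4 stromal and epithelial markers.

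Other groupings of the same libraries bear on the counts of separated bins and genes. For the 113 kb separating the genotypes over all 10 libraries, 3 of 36 groupings gave as much, the highest other giving 131 kb, so chance cannot be excluded. For the 1605 kb separating M1 and M2, 4 of 35 did, with a highest other of 3008 kb, and for the 8 genes separating M1 and M2, 8 of 35 did, with a highest other of 61 genes, so chance cannot be excluded for either. The grouping with the highest value in both set WT M1 replicates 1 and 2, KO M1 replicate 1 and WT M2 replicate 1 against the rest, which points to a structure of the libraries other than state. These are the 4 stimulated libraries with the lowest shares of tags in regions, 41.3% to 48.3% against 48.5% to 61.3%. The 2 genes covered in all 5 KO and no WT library, Olfr554 and Rab4a, were more than any other grouping gave, at 1 of 36 with a highest other of 1, a share under 0.05 that rests on a margin of 1 gene and on Rab4a values in WT just under the limit. The groupings were counted again under other settings. On autosomes they gave the same count and share. With 25% of the gene body 1 of 36 gave as many as the real 4, of which only Olfr554 is the same gene. Chance could not be excluded with equal numbers of regions by score (6 of 36 gave as many as the real 1) or tag count (4 of 36), with gene ends (17 of 36, highest other 4) or with the upper 50% by score, where the real 3 genes were covered in WT only (20 of 36, highest other 9). Whether chance is excluded thus depends on the setting.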

How the results depend on the processing

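Tests with both WT replicate 1 libraries left out, with 25% of the gene body, with gene ends, without flanks, with regions ranked by tag count and with the replicate block for single genes were chosen only after the result was seen. Of 584 alternative values for 46 results, 451 kept their direction, side of the threshold or size, 95 moved by more than the spread or by over 1.5 times, 27 reversed, 8 lost and 3 gained a p under the threshold. Some of the 451 could not change, such as M1 bins without an M0 or M2 library, or M1 against M2 results without an M0 library. The same holds for bins within M1 or M2 under the replicate block, so the 451 overstate how stable the results are. Of the 8 lost, 2 were Socs3 (35.2) and Egr2 (-17.9) with the upper 50% by score. The other 6 were Nos2, Socs3 and Egr2 without both WT replicate 1 libraries (84.7, 70.1 and -28.7 points) and with the replicate block, where so few arrangements cannot give an exact permutation p under 0.10 and 0.125. The 3 gained were the LPS and interferon list between states, at 2.25 genes with the upper 50% by score and with 25% of the gene body and 2 without WT M2 replicate 1 (exact permutation p = 0.0286 each). The 2 genes without WT M2 replicate 1 are Nos2 and Socs3. The reversed differences in region number, covered length and Jaccard index had exact permutation p of at least 0.20 under every alternative that reversed them. Depth and the lack of an input control limit all region calls, and the cause of the changes below was not tested except where fewer libraries have to share a bin or gene. Promoter windows of 2 kb and 5 kb were not run, for lack of strand, and the authors' tables could not be recomputed without a library.

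On autosomes alone the genotype difference was 1915 regions and 11.8 Mb. Without both WT replicate 1 libraries the genotype difference in regions was 1089, and the state differences were 799 regions and 0.340 Mb. With those 2 libraries left out, bins in KO only and WT only were 15243 and 25069 kb in M1, 34206 kb in WT only in M2, and 228 and 44 kb over all states; M1 only and M2 only held 5432 and 6419 kb and 22 and 105 genes. There the IL-4 list difference between states was 0.667, against 0.75 with 25% of the gene body, and cover of the M1 tables outside M1 differed by -1.41 and -0.270 points. With the upper 50% by score, KO only and WT only bins were 13911 and 11549 kb in M1 and 180 and 62 kb over all states, genes were 0 and 3, and M2 only genes 10. With merged regions the bins were 2285 and 2701 kb in M1, 5151 and 4452 kb in M2, 31.4 and 0 kb over all states, and 691 and 253 kb for M1 only and M2 only. Over all states, WT only bins were 4 kb at 90% cover and 0 kb in 5 kb bins, and without M0 the lengths were 485 and 380 kb. KO only genes numbered 1 with equal numbers of regions by score or by tag count and with gene ends, and 4 with 25% of the gene body. M1 only and M2 only genes numbered 15 and 10 with gene ends and 2 and 5 with 25% of the body. The M0 share kept by WT M1 was 76.6% and 79.8% with equal numbers of regions by score and by tag count, and that of KO M2 was 87.7% with bins called at 1 bp and 89.4% by tag count. At a false discovery rate under 0.05 the authors' tables held 0 regions for KO and 0 for WT in M1, and 1 and 2 in M2.

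Leaving out each library in turn, the genotype difference ran from -2344 (without WT M0) to 338 regions (without WT M1 replicate 1) and from -10.9 (without WT M0) to 1.20 Mb (without KO M2 replicate 2). The state difference ran from -1015 (without KO M1 replicate 1) to 1431 regions (without WT M1 replicate 1) and from -8.74 (without WT M2 replicate 2) to 3.61 Mb (without KO M2 replicate 2). KO only and WT only bins ran from 7345 to 27061 kb (without KO M1 replicate 1) and 5982 to 50904 kb (without WT M1 replicate 2) in M1, and from 13026 to 57603 kb and 11413 to 75981 kb in M2 (without WT M2 replicate 2). Over all states they ran from 118 (without WT M2 replicate 1) to 428 kb (without KO M1 replicate 1) and 11 (without KO M0) to 372 kb (without WT M0, where KO only was 302 kb). M1 only and M2 only bins ran from 1061 to 3322 kb (without WT M1 replicate 1) and 544 to 4159 kb (without WT M2 replicate 1). The Jaccard difference ran from -0.0498 (without KO M2 replicate 2) to 0.0632 (without WT M2 replicate 2) for genotype and from -0.00356 (without WT M1 replicate 2) to 0.0348 (without WT M2 replicate 1) for state. KO only genes ran from 2 to 9 (without KO M1 replicate 1), WT only genes from 0 to 1 (without WT M0), M1 only genes from 6 to 18 (without WT M2 replicate 2) and M2 only genes from 2 to 88 (without WT M2 replicate 1). Cover differences in the other states ran from -1.41 to 15.5 points and -0.270 to 12.2 for the M1 tables (without WT M2 replicate 1 and 2), and from -10.9 to 7.44 for the WT enriched M2 table (without WT M1 replicate 1 and 2). For the KO enriched M2 table they ran from 2.12 (without KO M1 replicate 2) to 7.08 points (without KO M1 replicate 1). The IL-4 list difference between states ran from -1.5 (without KO M2 replicate 2) to 0.833 (without WT M2 replicate 1).

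Using the replicate number as a replicate block changes only the arrangements, so the differences themselves could not move. The genotype differences stayed at -1019 regions and -4.72 Mb, and the state differences of -209 regions and -3.59 Mb had exact permutation p of 0.875. Nos2, Socs3 and Egr2 kept their differences of 82.7, 67.1 and -32.9 points, but 16 arrangements cannot give a p under 0.05, and none of the other results run with the block changed its call. Correlations of the replicate difference between groups ran from -0.0652 to 0.213, the highest falling to -0.00311 on autosomes, so the numbers were not taken to pair the samples across groups, although both WT replicate 1 libraries share the X chromosome pattern.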

Other observations

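The other-grouping test of the 7 libraries, the counts of genes shared with M0 and the genes named here were chosen only after the result was seen. Covered in both M0 libraries, both KO M2 libraries and no other library were 54 genes, against 0 for WT M2, WT M1 and KO M1 in place of KO M2. Among all 28 pairs of stimulated libraries the next highest count was 7. KO M2 libraries also had the highest shares of tags in regions of the stimulated libraries, 61.0% and 61.3%, near the 62.6% and 64.1% of M0. Elane, which encodes neutrophil elastase, had 93.3% and 100% of its body covered in M0, 52.5% and 99.1% in KO M2 and 0% in the other 6 libraries. Cish, a cytokine-inducible inhibitor of signalling (chromosome 9, 107296659 to 107302784), had 100% and 79.7% covered in M0 and 64.5% ± 0.427 in KO M2, against 31.1% ± 13.3 in WT M2 (SD, n = 2) and 0% to 31.9% in M1. Outside this group, the Polycomb gene Cbx2 had 81.4% and 81.5% of its body covered in M0 and between 8.16% and 42.1% in the stimulated libraries.

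Without WT M2 replicate 1, the library that shared least with its state, 88 genes were covered in the 3 remaining M2 libraries and in no M1 library, and 10 in the reverse direction. Besides Nos2 and Socs3 the 88 include Krt8 and Zap70 of the fixed lists, the heat shock gene Hspa1a, the endothelial nitric oxide synthase Nos3, the vitamin D receptor Vdr and the B cell genes Spib and Cd22. Of the 88 genes, 57 were covered in both M0 libraries, 20 in 1 of them and 11 in neither, and of the 10 genes 2 were covered in both M0 libraries. Of 35 groupings of these 7 libraries, 1 gave as many genes as the real 98, with a highest other of 64. That share excludes nothing, because the library was left out for its low similarity to its own state, which favours the real grouping. The remaining M2 libraries also had 56.5% to 61.3% of tags in regions against 45.0% to 48.5% in M1, so state and enrichment cannot be told apart for these genes.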
